A study of Mus musculus with 4 samples.

How the data were processed

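Single-cell RNA sequencing was available for 4 libraries of thymocytes from C57BL/6J mice aged 3 weeks, either wild type or PD-1 knockout per the labels. Per the labels' protocols, the thymi of 4 animals were pooled, CD8-bearing cells were depleted, and live cells were sorted as CD4+ HSA+ CD73− and either CD25− (CD4 single-positive thymocytes) or CD25+ (regulatory T cells and their CD25+ progenitors). The same protocol lists CD74 rather than CD73 among the stains, so whether CD73 was stained stays uncertain. Libraries were made with the 10x Genomics Next GEM Single Cell 5′ kit v2, per the same protocols. Each of the 4 combinations of 2 gates and 2 genotypes has 1 library, and whether both gates of a genotype came from the same pool of thymi is not given in the sources used here.

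The authors deposited, for each library, a matrix of UMI counts (unique molecular identifiers, which mark single captured transcripts) over 32285 genes and the barcodes it holds. The values are raw whole-number counts per gene and barcode with no normalization. Alignment was to mm10 with Cell Ranger 6.2.1, per the submitters' processing notes, whereas the file headers name Cell Ranger 6.1.2. The gene annotation used for counting and the rule by which barcodes were called cells are not given in the sources used here, and the lowest barcode in the deposited matrices held 500 UMIs. Gene positions were taken from GENCODE vM21 (GRCm38, the mm10 assembly), in which 32158 of the 32285 gene identifiers and 408 of 408 named genes were found.

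Barcodes with fewer than 500 genes or with 10% or more of their UMIs from mitochondrial genes were left out. Doublets were scored with Scrublet as implemented in scanpy, and the highest-scoring barcodes were removed at a rate of 0.8% per 1000 barcodes, which took 4.27% of WT CD25−, 6.89% of WT CD25+, 2.89% of knockout-labelled CD25− and 8.64% of knockout-labelled CD25+ cells. For clustering, counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used over all 4 libraries. Pdcd1, T and B cell receptor segments, sex-linked, mitochondrial and ribosomal protein genes were left out of the clustering. A cluster received a cell type name only where at least 3 markers fixed beforehand were among its 50 leading genes, ranked by fold with 5 CPM added and detected in at least 10% of its cells. Its top 10 genes were then searched for markers of other types. Clusters at Cd4 of at least 100 CPM and Trac of at least 50 CPM were called Cd4-expressing. These minimums were set after the data had been seen, and clusters below either minimum, apart from the cluster of double-positive-like cells, were called Cd4-low.

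UMIs were summed over the cells of a library, or of a cell class within it, and scaled by the sum over all genes to CPM, the usual unit of transcripts relative to depth. With 1 library per group no test between groups was run, so no p-value or standard error is given, and each comparison is of libraries, not of genotypes. Levels have exact Poisson intervals, ratios of levels have exact conditional binomial intervals, and shares of cells have exact Clopper-Pearson intervals, all at 95%. These intervals, and the upper limits of 3 counts given where a count was 0, cover counting error only. Differences between 2 shares have Newcombe intervals. Genes entered a comparison at a CPM of at least 20 in either library, and were counted as higher or lower where the CPM differed by at least 1.5-fold. Gene lists were summarised over members with at least 20 UMIs by the median log2 ratio, and by the percentile of that median among 10000 random lists of the same size matched in 20 bins of mean expression. Such a percentile describes these libraries and has no replicate behind it, and a list of unchanged genes can fall at any percentile. Shares of cells with a UMI were computed after each cell was thinned to 1500 UMIs, leaving out shallower cells: 537 of WT CD25−, 182 of WT CD25+, 93 of knockout-labelled CD25− and 203 of knockout-labelled CD25+ cells.

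The sample groups, comparisons, 27 gene lists, cell type markers and the rule for named genes were fixed before the data were examined, and 5 lists were added afterwards and are identified as such. The rule names, for each comparison, the 10 genes with the highest and the 10 with the lowest ratio among those that also had at least 100 UMIs over both libraries, whose counting interval excludes no difference and whose direction held with cells weighted equally. It leaves out Pdcd1, receptor segments, sex-linked, mitochondrial, ribosomal protein and hemoglobin genes and unnamed gene models. It adds 17 genes always reported and the 2 extreme members of each list. Where a gene lay outside the rule, the text says so.

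Alternatives tried were keeping doublets, a stricter cell filter (at least 1000 genes and under 5% mitochondrial UMIs), Leiden resolutions of 0.5 and 1.5, clustering without proliferation genes, and clustering of the CD25+ libraries alone. Scaling was varied by leaving mitochondrial, ribosomal protein and receptor segment genes out of the total, by centring on the median gene, and by weighting cells equally. A CPM minimum of 50, a minimum of 100 UMIs over both libraries in place of the CPM minimum, thinning to 1000 or 2500 UMIs or not at all, a minimum of 2 UMIs per positive cell, and leaving out clusters of other lineages were also run. Analyses of Cd4-expressing clusters alone, of every deposited barcode, of 1 Treg-like cluster with doublets kept and of shares outside the low-depth cluster were added after the data had been seen.

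The procedure was tested on simulated data drawn from the real means and library sizes with 200 genes changed. The simulated libraries were Poisson draws from shared means, so they held counting error and no variation between animals, sorts or preparations. The rates below therefore cannot tell how many real genes pass 1.5-fold through such variation. For the comparison of the CD25− libraries (6770 genes), the CD25+ libraries (6913) and the WT gates (7002), none of the unchanged genes passed 1.5-fold and all genes changed 2-fold or 4-fold were recovered, and the intervals covered the true ratio for 94.55% of genes in the CD25−, 95.2% in the CD25+ and 95.4% in the gate comparison. For a class the size of the Foxp3-richest cluster (6436 genes), 140 of 6241 unchanged genes passed 1.5-fold by counting error, and 56 of 59 genes changed 2-fold and 64 of 64 changed 4-fold were recovered. A single list of unchanged genes drawn in each simulation lay at the 92.6th (CD25−), 94.3th (CD25+), 21.9th (WT gates) and 39.0th percentile (cluster). Computations used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, statsmodels 0.14.6 and matplotlib 3.10.9.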

Results

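Transcripts were counted in single thymocytes of wild-type (WT) and PD-1 knockout-labelled mice, in a CD25− gate of CD4 single-positive thymocytes and a CD25+ gate meant to hold regulatory T cells (Tregs) and their precursors. Each of the 4 groups was 1 library from pooled thymi, so no difference below has a replicate check. After filtering, 2985 WT CD25− cells (13580881 UMIs, median 4497 per cell), 1716 knockout-labelled CD25− cells (11159298 UMIs, median 6299), 7649 WT CD25+ cells (54061390 UMIs, median 5808) and 9236 knockout-labelled CD25+ cells (68989300 UMIs, median 5962) were kept. The filter on genes per cell left out 34.3% of WT and 42.9% of knockout-labelled CD25− barcodes, against 1.59% and 1.38% in the CD25+ libraries.

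Pdcd1, the targeted gene, encodes the inhibitory receptor PD-1 (ENSMUSG00000026285, minus strand of chromosome 1, 94038305 to 94052553, mm10). It was at 18.3 CPM in WT CD25− cells (248 UMIs, interval 16.1 to 20.7) and at 27.2 CPM in knockout-labelled CD25− cells (304 UMIs, 24.3 to 30.5). In the CD25+ gate it was at 16.0 CPM in WT (866 UMIs, 14.97 to 17.1) and at 18.9 CPM in the knockout-labelled library (1302 UMIs, 17.9 to 19.9). Over all kept cells Pdcd1 transcripts were therefore not lower in either library labelled knockout, where the level was 1.49-fold (1.26 to 1.77) and 1.18-fold (1.08 to 1.29) that of WT. Cell classes differed: in the CD25− gate the level was 1.65-fold (1.29 to 2.12) that of WT in immature CD4 single-positive-like and 1.91-fold (1.22 to 3.07) in T cell receptor-signalled-like cells, but 0.662-fold (0.426 to 1.01) in mature CD4 single-positive-like cells (6.61 against 9.98 CPM, 35 and 65 UMIs). In the CD25+ gate it was 1.43-fold (1.20 to 1.71) in T cell receptor-signalled-like and 0.715-fold (0.263 to 1.68) in mature cells, the latter from 7 and 27 UMIs. No difference was detectable there in immature (1.03-fold, 0.575 to 1.82, 22 and 34 UMIs) or Treg-like cells (0.979-fold, 0.604 to 1.56). The labels do not give the deleted part of the gene, and 5′ reads can lie outside a deletion, so these levels say nothing about the genotype. Libraries are called knockout-labelled throughout, and every direction below rests on those labels.

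The first comparison asked what the CD25 gate separated in WT thymus. The CD25+ library held Il2ra, the α chain of the IL-2 receptor and the sorted antigen (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), at 1193 CPM, 506-fold (359 to 740) above the CD25− library. Foxp3, the transcription factor of Tregs (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), was 5.46-fold (4.41 to 6.84) higher and Ctla4, an inhibitory receptor of Tregs, 4.36-fold (3.86 to 4.94) higher. Most Ctla4 UMIs of the CD25+ library lay outside Treg-like cells, which held 1068 of 4792. Yet Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221) was at 47.1 CPM in the CD25+ library against 353 CPM in the CD25− library, and Trac, the constant segment of the T cell receptor α chain, at 25.4 against 178 CPM. Genes of early thymocytes were high there: Ptcra, the pre-T cell receptor α chain, was at 460 CPM against 1.03, Rag1, a subunit of the V(D)J recombinase, at 247 against 2.14, and Dntt, which adds nucleotides at V(D)J joints, at 1208 against 25.0 CPM.

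Of 7495 genes, 1500 were at least 1.5-fold higher and 1342 at least 1.5-fold lower in the WT CD25+ than in the WT CD25− library. At the top stood Bst1, a cell surface ectoenzyme, 1467-fold higher (263 to 57936, 1 UMI in the CD25− library), and the imprinted RNA H19, at least 940-fold higher. Cdkn1a, a cyclin-dependent kinase inhibitor, was 895-fold higher (248 to 7390), Smim5 811-fold (146 to 32049), Camkv 700-fold (126 to 27653), Scin, an actin-severing protein, 582-fold (161 to 4809) and Scn4b 573-fold (103 to 22643), each against 1 or 2 UMIs. Slc5a9, Mpzl2 and Khdc1a, with no UMI in the CD25− library, were at least 740-fold, 714-fold and 605-fold higher. Lowest in the CD25+ library were Rflnb (21.0-fold), Vipr1, a receptor of vasoactive intestinal peptide (20.2-fold), Hs3st3b1 (20.1-fold), Tdrp (16.7-fold), Acvrl1 (16.0-fold), the chromatin remodeller Chd7 (15.9-fold), Ampd1 (14.5-fold), Gramd3 and Tmie (both 13.0-fold) and Als2cl (12.8-fold). Socs2, a target of STAT5, was 39.4-fold higher, Cish 2.84-fold, Ikzf2 2.59-fold and Cd24a, the sorted antigen HSA, 14.1-fold higher. Cd5, whose level follows T cell receptor signal strength, was 5.06-fold lower, with Nr4a1 2.18-fold, Bcl2 2.05-fold and Cd69 1.67-fold lower. In Cd4-expressing cells the log2 ratio of Cd5 (0.10), Nr4a1 (1.20) and Cd69 (0.47) had the opposite sign.

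By gene group, all 18 proliferation genes were higher in the WT CD25+ library (median log2 ratio 1.29, 100th percentile of random lists), as were 11 of 15 Treg signature genes (1.14, 100th percentile), 7 of 10 double-positive thymocyte markers (3.65, led by Rag2) and 6 of 6 γδ T cell markers (3.53). Lower double-positive markers included Cd8b1 (−2.15, 11.1 against 49.4 CPM) and Cd8a (2.39 against 8.62 CPM). Rag1, Rag2 and Dntt, on that list, are also on the double-negative list below. Mature thymocyte and egress genes were lower in 10 of 12 (−1.71, lowest S1pr1, a receptor for thymic exit), interferon response genes in 12 of 12 (−1.91), helper lineage regulators in 13 of 16 (−1.08, lowest Zbtb7b at −3.49, a regulator of the CD4 lineage) and T cell receptor response genes in 13 of 20 (−0.78). Gm42418, a gene model over ribosomal RNA sequence and a sign of RNA quality, was at 7268 CPM in the WT CD25+ and 33269 CPM in the WT CD25− library. Markers of myeloid and dendritic cells were higher in 8 of 10 (1.36), with Lyz2 at 24.9 against 0.663 CPM. In the knockout-labelled pair the gates lay apart by a similar number of genes, 1580 higher and 1379 lower of 7498, with Ptcra 1361-fold (532 to 4997) higher and Foxp3 1.497-fold (1.22 to 1.85) higher in the CD25+ library.

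Clustering placed 99.5% of WT and 99.7% of knockout-labelled CD25− cells in Cd4-expressing clusters. In the CD25+ libraries these clusters held 1707 of 7649 WT cells (22.3%, 21.4 to 23.3) and 1059 of 9236 knockout-labelled cells (11.5%, 10.8 to 12.1). Cd4-low clusters held the other CD25+ cells but for a small double-positive-like cluster, 76.9% in WT and 87.9% in the knockout-labelled library. The largest Cd4-low clusters were each nearly particular to a single library. The first, with Scn4b and Emid1 among its leading genes, held 3626 WT (47.4%) and 134 knockout-labelled CD25+ cells (1.45%). The second, led by Cldn4 and Atoh8, held 139 (1.82%) and 3395 (36.8%). Ratios over Cd4-low cells therefore also compare different clusters. The clustering did not adjust for library, and these 2 clusters had similar levels of Ptcra (844 and 968.5 CPM) and Rag1 (476.5 and 506 CPM). Dntt lay further apart (1638 and 1073 CPM). Different kinds of cells, and 1 kind split by differences between the libraries, cannot be told apart here. A list of 18 double-negative thymocyte markers, written after the clusters had been seen, was higher in the WT CD25+ than the WT CD25− library for 18 of 18 members (4.70), and 10 of 10 markers of αβ T cells on another such list were lower (−2.39).

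**Figure D1:**
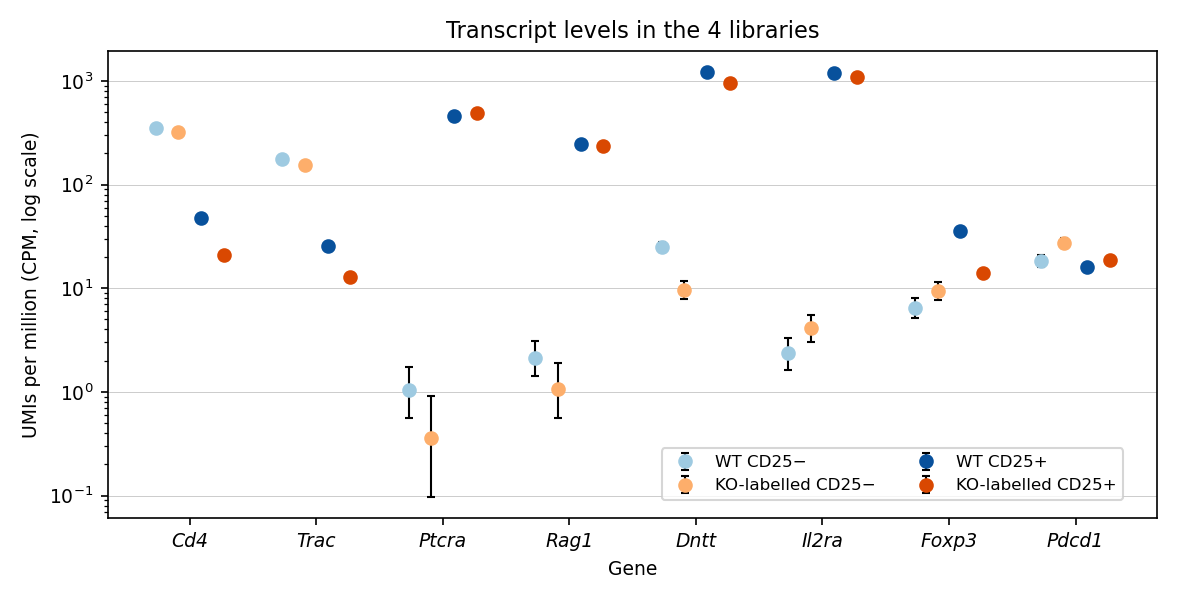
Levels of 8 genes in the 4 libraries, in CPM on a log axis, with points for the summed cells of each library and bars for exact 95% Poisson intervals. Cd4 and Trac were lower, and Ptcra, Rag1, Dntt and Il2ra higher, in both CD25+ libraries than in both CD25− libraries, while Pdcd1 lay between 16.0 and 27.2 CPM in all 4.

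Cd4-expressing cells were also compared alone, a restriction chosen after the data had been seen. Of 6972 genes, 434 were at least 1.5-fold higher and 577 lower in the WT CD25+ than in the WT CD25− gate, with Gm42418 at 6366 against 33315 CPM. Genes of Tregs and of T cell receptor response were among the higher ones. Xcl1, a chemokine, was 435-fold (186 to 1342) higher, Il2ra 111-fold, Lrrc32, the surface docking protein of latent TGF-β on Tregs, 69.1-fold, Cd83 55.0-fold and Foxp3 30.7-fold (24.8 to 38.4) higher. Rln3 (42.2-fold), Pdzk1ip1 (25.7-fold), the transcription factor Bhlhe40 (17.9-fold), Lad1 (17.8-fold) and Hopx (17.0-fold) completed the highest genes. Il2rb (8.50-fold), Ikzf2 (8.72-fold), Tnfrsf4 (7.71-fold), Cish (7.52-fold), Ctla4 (6.79-fold), Tnfrsf18 (4.01-fold), Nr4a1 (2.29-fold) and Pdcd1 (2.22-fold) were also higher. Gzma, a granule protease, was 43.1-fold lower (19.6 to 118), followed by Ggt5 (5.20-fold), Rflnb (4.31-fold), Vipr1 (3.96-fold), Rapgef4 (3.73-fold), Hs3st3b1 (3.72-fold), Chd7 (3.36-fold), Hspa1b (3.26-fold) and Oas2 (3.19-fold). All 15 Treg signature genes were higher (median 2.76), as were 12 of 12 NF-κB response genes (0.54), 7 of 8 TNF receptor family genes (1.43) and 16 of 20 T cell receptor response genes (0.52). For the receptor response list this is opposite to the direction over all cells.

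The comparison of knockout-labelled with WT CD25− cells asked how PD-1 loss bears on conventional CD4 thymocytes. Akr1c18, a steroid-reducing enzyme, was 24.4-fold higher in the knockout-labelled library (43.1 against 1.77 CPM, interval 16.2 to 38.5), and Nrgn, a calmodulin-binding protein, 3.77-fold (3.40 to 4.20). Hspa8, the constitutive HSP70 chaperone, was 3.49-fold lower (486 against 1697 CPM, 3.39 to 3.60) and Thy1, a surface glycoprotein of T cells, 3.46-fold lower (117 against 405 CPM, 3.26 to 3.68). Il2ra was 1.75-fold (1.09 to 2.84, 46 and 32 UMIs), Cish, a STAT5 target, 1.51-fold (1.24 to 1.85) and Foxp3 1.45-fold (1.08 to 1.95) higher. Treg-like cells, 26 knockout-labelled and 20 WT, held 46 of 105 and 34 of 88 Foxp3 UMIs. Within them Foxp3 (309.5 against 395 CPM) and Il2ra (47.1 against 128 CPM) were not higher, with overlapping counting intervals. In mature CD4 single-positive-like cells Foxp3 (6.61 against 4.45 CPM, overlapping intervals) and Cish (20.6 against 11.7 CPM) were higher. Proliferation and interferon response genes were higher as groups. Gm42418 was at 17878 CPM in the knockout-labelled and 33269 CPM in the WT CD25− library.

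Of 6880 genes, 121 were at least 1.5-fold higher and 86 at least 1.5-fold lower in knockout-labelled CD25− cells. The split depended on the scaling: it was 137 higher and 63 lower with mitochondrial, ribosomal protein and receptor segment genes out of the total, 140 and 61 centred on the median gene, 113 and 49 under the stricter cell filter, and 178 and 250 with cells weighted equally. The other genes highest in the knockout-labelled library were the glutathione transferase Gsta4 (3.65-fold), the linker histone H1f0 (3.64-fold), Hist1h2af (3.54-fold), the interferon-induced genes Ifi44 (3.53-fold) and Iigp1 (3.37-fold), Mid1, a ubiquitin ligase (3.34-fold), and Ms4a4c (2.98-fold). Dntt (2.58-fold), Irf2bp2 (2.54-fold), Traf1, an adaptor of TNF receptors (2.26-fold), Vav3 (2.01-fold), Banp (1.96-fold), Parp6 (1.92-fold), Hsph1, an HSP110 chaperone (1.91-fold), and Myo10 (1.90-fold) were lower. Tnfrsf4 (1.41-fold), the survival factor Bcl2 (1.30-fold), Il2rb (1.26-fold), Ikzf2 (1.22-fold), Cd69 (1.19-fold), Nr4a1 (1.12-fold) and Tnfrsf18 (1.10-fold) were higher, and Ctla4 (1.43-fold, 1.17 to 1.75) and Cd5 (1.19-fold) lower. In mature CD4 single-positive-like cells, though, Nr4a1 was lower in the knockout-labelled library (64.8 against 91.5 CPM), as was Cd69 (78.0 against 92.7). In T cell receptor-signalled-like cells Nr4a1 (730 against 469 CPM) and Cd69 (251 against 198) were higher. Cd69 was also higher in immature CD4 single-positive-like cells (241 against 160). For Bcl2l11, Cd24a and Socs2 no difference was detectable at this depth.

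All 18 proliferation genes were higher in knockout-labelled CD25− cells (median log2 ratio 0.50, 100th percentile), among them Pclaf (0.86) and the cyclin Ccnb1 (1.73-fold). All 12 interferon response genes were higher (0.27, 100th percentile), with Ifit3 1.45-fold and Irf7 1.34-fold. Higher members made up 10 of 13 in the Treg signature (0.28, 99.9th percentile, highest Tigit at 0.99, lowest Nrp1 at −0.64), 14 of 20 among T cell receptor response genes (0.17, highest Irf8 at 0.96, lowest Irf4 at −0.47), 8 of 11 IL-2 and STAT5 targets (0.25), 6 of 8 TNF receptor genes (0.22, Tnfrsf9 at 60.4 against 34.9 CPM) and 11 of 13 oxidative phosphorylation genes (0.12). Heat shock and dissociation stress genes were lower in 9 of 12 (−0.25, 0.13th percentile). Medians of the mature and immature thymocyte, glycolysis and PD-1 pathway lists changed sign with the scaling and are given no direction.

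Shares of cell classes were also compared in the CD25− gate. Mature CD4 single-positive-like cells made up 44.2% of knockout-labelled and 36.7% of WT cells, immature CD4 single-positive-like cells 28.0% and 22.9%, and T cell receptor-signalled-like cells 4.72% (3.77 to 5.83) and 2.71% (2.16 to 3.36). A Cd4-expressing cluster of low depth (median 1602 UMIs) held 15.1% of knockout-labelled and 33.2% of WT cells, so the other shares move with cell quality. Outside that cluster, a restriction chosen after the data had been seen, the order of the mature and immature shares turned within overlapping counting intervals: mature cells were 52.1% (49.5 to 54.7) of knockout-labelled and 54.9% (52.7 to 57.1) of WT cells, and immature cells 33.0% and 34.3%. These shares are therefore given no direction. T cell receptor-signalled-like cells were there 5.56% (4.44 to 6.86) and 4.06% (3.24 to 5.03). Genes that lead these clusters also differed between the libraries, such as Rflnb (log2 ratio −0.54) and Itm2a (0.42), and the shares can move with them. Treg-like cells numbered 26 of 1716 (1.52%, 0.992 to 2.21) and 20 of 2985 (0.670%, 0.410 to 1.03). Outside the low-depth cluster they were 1.78% (1.17 to 2.60) of knockout-labelled and 1.00% (0.614 to 1.55) of WT cells, with overlapping counting intervals.

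Il2, the growth factor named in the aim of the series (ENSMUSG00000027720, chromosome 3, 37120523 to 37125959), was nearly undetected. There were 2 UMIs among WT CD25− cells (0.147 CPM) and 0 among knockout-labelled CD25− cells, which allows up to 0.269 CPM, so no fold is given. After thinning to 1500 UMIs, 1 of 2448 WT CD25− cells (0.0409%) and 0 of 1623 knockout-labelled CD25− cells had an Il2 UMI, the latter allowing a share of up to 0.185%. Without thinning the counts were 2 of 2985 and 0 of 1716 cells, and in the Cd4-low cells of WT CD25+, as a background, 0 of 5885 (median depth 6128 UMIs), against 4 of 8119 in those of the knockout-labelled CD25+ library (median depth 6114 UMIs). In the CD25+ gate 7 UMIs lay in 4 WT cells, all of them T cell receptor-signalled-like, and 6 UMIs in 6 knockout-labelled cells, 4 of them Cd4-low. The log2 ratio of Il2 there was −0.57 with an interval from −2.42 to 1.22. No difference in Il2 was detectable at this depth in either gate.

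The comparison of CD25+ cells asked how PD-1 loss bears on thymic Treg development. Treg-like cells made up 680 of 7649 WT CD25+ cells (8.89%, 8.26 to 9.55) and 359 of 9236 knockout-labelled cells (3.89%, 3.50 to 4.30), a difference of −5.00 percentage points (−5.76 to −4.26). This class comes from the clustering of all 4 libraries, and clustering the CD25+ libraries alone gave no cluster that met the rule for Treg-like cells. Foxp3 was 2.51-fold lower in the knockout-labelled library (14.1 against 35.4 CPM, 2.32 to 2.72). After thinning to 1500 UMIs, 5.72% of WT (5.20 to 6.27) and 2.52% of knockout-labelled cells (2.21 to 2.87) had a Foxp3 UMI, against 0.294% and 0.213% of Cd4-low cells, where median depths were 6185 and 6192 UMIs. Unthinned shares were 8.88% and 4.21%.

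These shares go with the different content of Cd4-expressing cells in the CD25+ libraries, 22.3% in WT and 11.5% in the knockout-labelled library. Taken over Cd4-expressing cells alone, Treg-like cells made up 39.8% (37.5 to 42.2) in WT and 33.9% in the knockout-labelled library, a difference of −5.94 points (−9.58 to −2.23), and Foxp3 was 1.34-fold lower (150 against 201 CPM, 1.23 to 1.45). Within Treg-like cells Foxp3 was 1.09-fold lower (523 against 572 CPM, 1.00 to 1.19). In T cell receptor-signalled-like CD25+ cells Foxp3 was lower by a log2 ratio of −0.997 (15.6 against 31.2 CPM, 42 and 100 UMIs). Mature CD4 single-positive-like CD25+ cells held it at 37.7 against 27.3 CPM (16 and 32 UMIs), with overlapping counting intervals. T cell receptor-signalled-like cells made up 6.39% of all WT and 4.39% of all knockout-labelled CD25+ cells, but of Cd4-expressing cells 38.2% (35.3 to 41.3) in the knockout-labelled library and 28.7% (26.5 to 30.9) in WT. Mature CD4 single-positive-like cells were 8.12% and 13.9% of Cd4-expressing cells in the knockout-labelled and WT libraries, and immature ones 9.54% and 9.96%. Genes that lead a cluster can move its share: of those leading the Treg-like cluster Gsta4 was 2.42-fold higher within it in the knockout-labelled library, and of those leading the receptor-signalled cluster Xcl1 was higher by a log2 ratio of 0.70.

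**Figure D2:**
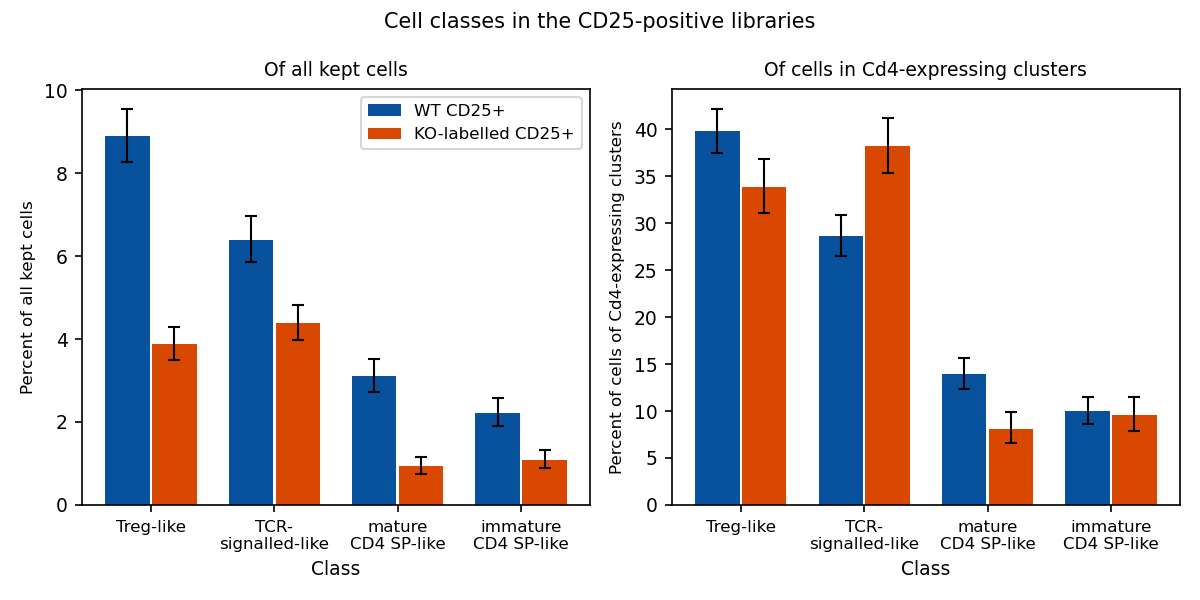
Shares of 4 named cell classes in the CD25+ libraries, in percent of all kept cells (left) and in percent of cells of Cd4-expressing clusters (right), with exact 95% binomial intervals as bars. Treg-like cells were fewer in the knockout-labelled library by either denominator, while T cell receptor-signalled-like cells were fewer of all cells (4.39% against 6.39%) and more of Cd4-expressing cells (38.2% against 28.7%).

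Over all CD25+ cells, 122 of 7107 genes were at least 1.5-fold higher and 165 at least 1.5-fold lower in the knockout-labelled library. With mitochondrial, ribosomal protein and receptor segment genes out of the total the split was 150 higher and 135 lower, centred on the median gene 155 and 133, with cells weighted equally 187 and 169, and in Cd4-expressing cells 86 and 75 of 6793 genes. The class Ib MHC genes H2-Q6 (8.90-fold, 7.45 to 10.7) and H2-Q7 (4.13-fold) were among the highest, with Mid1 (5.72-fold), the interferon-induced genes Iigp1 (3.78-fold), Oas1a (3.60-fold), Ifitm3 (2.43-fold) and Oasl2 (2.37-fold), the sorting receptor Sorl1 (3.15-fold), Fbp1 (2.47-fold) and Hist1h2af (2.35-fold). Hspa8 was 5.19-fold lower (528 against 2742 CPM, 5.13 to 5.25), Nefh 3.73-fold, Scin 3.59-fold, Kremen1 3.22-fold, Thy1 3.21-fold, Scn4b 3.07-fold, the chemokine receptor Ccr7 2.72-fold, Hsph1 2.71-fold, S1pr1 2.69-fold and Gimap3 2.68-fold lower. In Cd4-expressing cells Scn4b was higher (log2 ratio 1.23), and Ifitm3 was at −0.20, with a counting interval that spans 0.

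Treg signature genes were lower in 12 of 15 members over all knockout-labelled CD25+ cells (median −0.52, 0th percentile), whereas in Cd4-expressing cells the median was near 0 (0.08, 89.3th percentile, 9 of 15 higher). T cell receptor response genes were lower in 18 of 20 over all cells (−0.48), with a median near 0 in Cd4-expressing cells (0.06, 89.8th percentile, 13 of 20 higher). IL-2 and STAT5 targets were lower in 12 of 12 over all cells (−0.15, 5.29th percentile). They were lower in 8 of 12 in Cd4-expressing cells (−0.13, 4.55th percentile) and higher in 7 of 12 in Treg-like cells (0.07, 89.6th percentile). Il2rb (1.84-fold), Tnfrsf4 (1.71-fold), Tnfrsf18 (1.44-fold), Cish (1.39-fold), Nr4a1 (1.34-fold), Ikzf2 (1.26-fold), Cd24a (1.24-fold) and Bcl2l11 (1.13-fold) were lower over all cells and not in Cd4-expressing cells. Cd5 (1.94-fold), Socs2 (1.38-fold), Bcl2 (1.31-fold), Cd69 (1.21-fold), Ctla4 (1.13-fold) and Il2ra (1.09-fold) were also lower over all cells. The groups of immature thymocyte genes (10 of 10 lower, −0.29), TNF receptors (8 of 9 lower, −0.52), NF-κB response (9 of 12 lower, −0.40), apoptosis (13 of 15 lower, −0.30) and myeloid markers (9 of 10 lower, −0.48, H2-Eb1 9.24-fold) were lower over all cells. In Cd4-expressing cells, of which the knockout-labelled library held fewer, the medians of TNF receptors (0.08, 87.5th percentile, 7 of 8 higher) and apoptosis genes (0.07, 86.2th percentile, 9 of 15 higher) were near 0, and NF-κB response genes were lower in 8 of 12 (−0.11). The median of TNF receptors was 0.18 (99.5th percentile) within Treg-like cells and 0.16 (97.95th percentile) in the other Cd4-expressing cells. Over all CD25+ cells outside the Treg-like and double-positive-like clusters it was −0.35 (0.03th percentile, 8 of 9 lower). Proliferation genes were higher in 18 of 18 over all cells (0.42) and in 12 of 18 in Cd4-expressing cells (0.05), and interferon response genes in 9 of 12 (0.48, 100th percentile) and 10 of 12 (0.19). In T cell receptor-signalled-like CD25+ cells only 4 of 10 interferon response genes were higher (−0.10, 21.1th percentile), so that direction was not seen in this class.

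In Cd4-expressing CD25+ cells Akr1c18 was again far apart, at 209 UMIs in the knockout-labelled and 6 in the WT library (54.3-fold, 24.5 to 150). Penk, the enkephalin precursor, was 4.27-fold, Mid1 4.39-fold, Iigp1 3.76-fold, Tmod1 2.74-fold, Ly6c1 2.55-fold, the cholesterol exporter Abca1 2.49-fold, Gsta4 2.45-fold, the orphan nuclear receptor Nr4a2 2.41-fold and the cold-inducible RNA-binding protein Rbm3 2.31-fold higher. Nefh (5.13-fold), Thy1 (5.09-fold), Hspa8 (4.36-fold), Banp (2.31-fold), Mta1 (2.18-fold), Mpi (2.04-fold), Hsph1 (1.98-fold), Acvrl1 and Selenop (both 1.93-fold) and Egln1 (1.90-fold) were lower. Pdcd1 (1.48-fold), Bcl2l11, a proapoptotic protein (1.41-fold), Nr4a1 (1.33-fold), Cd24a (1.24-fold), Cish (1.16-fold) and Tnfrsf4 (1.13-fold) were higher, and Cd69 (1.23-fold), Ctla4 (1.21-fold), Cd5 (1.16-fold) and Bcl2 (1.13-fold) lower. All 12 mature thymocyte and egress genes were lower (median −0.36, 0th percentile), including Ccr7 (−0.52), S1pr1 (−0.51) and their regulator Klf2 (−0.47), and 6 of 9 immature thymocyte genes were higher (0.26, 99.95th percentile). Among these cells the mature CD4 single-positive-like share was also lower (8.12% against 13.9%) and the T cell receptor-signalled-like share higher (38.2% against 28.7%). With cells weighted equally the median of the mature list was −0.17. Within single classes 8 of 12 mature genes were lower in Treg-like cells (−0.09, 12.5th percentile) and 11 of 12 in T cell receptor-signalled-like cells (−0.30, 0.12th percentile). Immature thymocyte genes were higher in 4 of 8 in T cell receptor-signalled-like cells (0.03), and in Treg-like cells their median changed sign with the scaling.

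Within Treg-like cells of the CD25+ gate, 199 of 6506 genes were at least 1.5-fold higher and 225 lower in the knockout-labelled library. With doublets kept the numbers were 164 and 102, but a second cluster then joined the class, in which 133 of 134 WT and 126 of 126 knockout-labelled cells had been called doublets. Without that cluster they were 176 and 205. In simulated data of this size 140 unchanged genes passed 1.5-fold by counting error alone. Penk was 6.22-fold (4.31 to 9.15) and Ly6c1 4.07-fold higher, and interferon-induced genes were prominent: Iigp1 (4.17-fold), Oas1a (3.53-fold), Ifi208 (2.62-fold) and Tgtp1 (2.42-fold). Igfbp4 (2.55-fold), Klhdc2 (2.49-fold), Gsta4 (2.42-fold) and Rbm3 (2.40-fold) were higher too. Hspa8 was 4.21-fold (3.86 to 4.60), Hsph1 3.80-fold (2.45 to 6.15), Thy1 3.79-fold, Banp 2.46-fold, the CD30 ligand Tnfsf8 2.41-fold, Txlng 2.32-fold, Acad9 2.28-fold, Mta1 2.17-fold, S100a11 2.17-fold and Foxj2 2.08-fold lower.

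Among genes of Treg identity, Ikzf2, encoding Helios, was 1.43-fold lower in knockout-labelled Treg-like cells (596 against 851 CPM, 1.32 to 1.54). Cish was 1.46-fold (1.29 to 1.65), Tnfrsf4 1.26-fold, Il2rb 1.21-fold, Tnfrsf18 1.20-fold and Il2ra 1.10-fold higher. Tnfrsf4, Il2rb and Tnfrsf18 lost this direction where the cluster of called doublets joined the class, and not with doublets kept in the main Treg-like cluster alone. Cd69 (1.22-fold), Bcl2 (1.19-fold) and Cd5 (1.17-fold) were lower, and for Ctla4, Nr4a1 and Pdcd1 (18.9 against 19.4 CPM) no difference was detectable. Treg signature genes were higher in 10 of 14 (median 0.17, 99.9th percentile), interferon response genes in 9 of 12 (0.49, 100th percentile) and TNF receptor genes in 6 of 8 (0.18). T cell receptor response genes were lower in 11 of 19 (−0.14, 6.48th percentile, and −0.02 with cells weighted equally), helper lineage regulators in 9 of 12 (−0.19), NF-κB response genes in 9 of 12 (−0.18) and heat shock genes in 8 of 10 (−0.33, 0.01th percentile).

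In the other CD25+ cells, outside the Treg-like and double-positive-like clusters, 104 of 7081 genes were at least 1.5-fold higher and 131 lower in the knockout-labelled library. The split was 133 and 108 with the reduced total, 140 and 102 centred on the median gene and 169 and 132 with cells weighted equally. H2-Q6 (10.8-fold), Mid1 (5.60-fold), H2-Q7 (5.29-fold), Iigp1 (4.46-fold), Sorl1 (3.99-fold), Oas1a (3.78-fold), Ifitm3 (2.62-fold), Oasl2 (2.59-fold) and Fbp1 (2.38-fold) were higher. Hspa8 (5.30-fold), Nefh (3.80-fold), Scin (3.71-fold), Kremen1, a receptor of the Wnt inhibitors of the Dickkopf family (3.33-fold), Thy1 (3.30-fold), Scn4b (3.22-fold), Ccr7 (2.85-fold), Emid1 (2.79-fold), Gimap3 (2.76-fold) and Gimap4 (2.75-fold) were lower. Foxp3 (1.76-fold), Cd5 (1.80-fold), Tnfrsf4 (1.62-fold) and Il2rb (1.52-fold) were lower over these cells. Interferon response genes were higher in 11 of 12 (median 0.83) and proliferation genes in 18 of 18 (0.37), and T cell receptor response genes were lower in 19 of 20 (−0.45). Among the Cd4-expressing part of these cells, 99 of 6847 genes were higher and 136 lower, with Akr1c18 47.3-fold higher and mature thymocyte and egress genes lower in 12 of 12 (−0.57, and −0.31 with cells weighted equally). Mature CD4 single-positive-like cells were 86 of 700 knockout-labelled and 238 of 1027 WT cells of that part. There the medians of T cell receptor response genes (0.08, 93.3th percentile, 12 of 20 higher) and proliferation genes (−0.08, 8.14th percentile, 12 of 18 lower) were near 0, so the directions over all the other cells were not seen. Tnfrsf4 (log2 ratio 0.17), Il2rb (0.17) and Emid1 (0.94) were higher and Ifitm3 lower (−0.72) in that part.

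**Figure D3:**
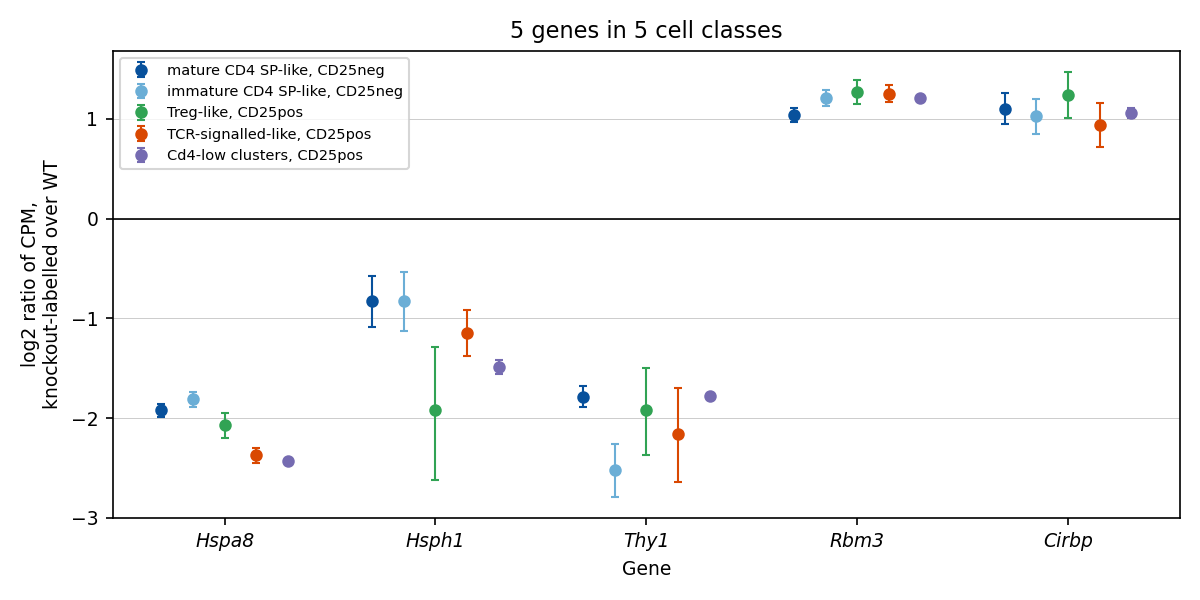
Log2 ratio of CPM, knockout-labelled over WT, of 5 genes in 5 cell classes, with exact 95% conditional binomial intervals as bars; SP is single-positive. Hspa8, Hsph1 and Thy1 were lower and Rbm3 and Cirbp higher in all 5 classes of the knockout-labelled libraries, with Hspa8 between −1.81 and −2.43.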

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

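The tests of the pattern weighed here were chosen only after the result had been seen.

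For 10 of the genes always reported, the knockout-labelled library was higher than WT in the CD25− gate and lower in the CD25+ gate. The difference between the gates in log2 ratio, CD25+ minus CD25−, was −1.87 for Foxp3, −1.27 for Tnfrsf4, −1.21 for Il2rb, −1.07 for Cish, −0.93 for Il2ra, −0.77 for Bcl2, −0.66 for Tnfrsf18, −0.61 for Ikzf2, −0.58 for Nr4a1 and −0.52 for Cd69. These differences were not tested, since each group is 1 library. In Cd4-expressing CD25+ cells Il2rb, Cish, Tnfrsf18, Tnfrsf4, Ikzf2 and Nr4a1 were not lower in the knockout-labelled library, whereas Foxp3, Bcl2 and Cd69 were.

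Most CD25+ cells carried few Cd4 and Trac UMIs although the gate was for CD4 protein. Low depth of these cells is argued against, since their median UMI count was at least 1.27 times that of the Cd4-expressing cells in both CD25+ libraries. The Cd4-low cells had little Cd8b1, at 0.308% of its level in the double-positive-like cluster (1.77 against 575 CPM). As a test of double-positive thymocytes this is weak, because that cluster, named from markers that include Cd8b1, had been left out beforehand. Double-negative thymocytes are a candidate source, although a CD4 gate would remove such cells. Leaving out genes already seen to lead the clusters, the lower of the medians of double-negative markers in Cd4-low over Cd4-expressing cells was 4.90 (log2). Rag2, at 115 against 0.540 CPM in WT, was kept although it already led another list. The list was written after the clusters had been seen. All its members were already higher in the WT CD25+ library, so this value describes the cells and cannot decide their source. Whether the cells were wrongly gated or carried CD4 protein stays open, and a biological difference in their number between the genotypes was not tested.

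Among the barcodes left out for fewer than 500 genes, Cd4 was at 203 CPM in the WT and 148 CPM in the knockout-labelled CD25− library, above the limit that a count of 0 allows, against 353 and 319 CPM in the kept cells. Gm42418 took 26.6% and 19.4% of the UMIs of these barcodes, against 3.33% and 1.79% in kept cells, and their median mitochondrial share was 20.3% and 29.2%.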

How the results depend on the processing

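The alternatives of Cd4-expressing clusters, every deposited barcode, and 1 Treg-like cluster with doublets kept were chosen after the data had been seen. No paired analysis was run, because each group has a single library. A clustering of the CD25+ libraries alone gave no cluster that met the rule for Treg-like cells, so it has no values. For each shift below the cause was not tested, except that a CPM minimum of 50 leaves fewer genes to count.

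Over all CD25+ cells (3.89% against 8.89%), the share difference of Treg-like cells stayed between −5.00 and −5.54 points in the alternatives that gave values. These were Leiden resolutions of 0.5 and 1.5, no proliferation genes, doublets kept (2 clusters) and the stricter cell filter. Over Cd4-expressing cells, an unlike denominator, it was −5.94 points (33.9% against 39.8%), a smaller relative change. Under the stricter filter the difference there was −4.67 points (−8.61 to −0.668). The Foxp3 ratio of the CD25+ libraries was −1.18 with cells weighted equally and −0.42 in Cd4-expressing clusters. The difference in the share of cells with a Foxp3 UMI was −4.15 points thinned to 2500 UMIs, −4.67 not thinned, −1.28 at a minimum of 2 UMIs and −5.41 in Cd4-expressing clusters. Il2 UMIs in the knockout-labelled CD25+ library numbered 2 in Cd4-expressing clusters.

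With a CPM minimum of 50, 51 genes were higher and 36 lower in the CD25− comparison, 46 and 78 in the CD25+ comparison, 881 and 865 between the WT gates, 44 and 52 in Treg-like cells and 43 and 64 in the other CD25+ cells. With a minimum of 100 UMIs over both libraries in place of the CPM minimum there were 333 and 246 in the CD25− and 530 and 623 in the CD25+ comparison, 3084 higher between the WT gates, 112 higher in Treg-like cells against 199 as reported, and 496 and 549 in the other CD25+ cells. With cells weighted equally, 250 were lower in the CD25− comparison, 187 higher in the CD25+ comparison and 169 higher in the other CD25+ cells. The stricter cell filter left 49 lower in the CD25− comparison, and keeping doublets, with which a second cluster joined the class, left 102 lower in Treg-like cells, against 205 without that cluster. In Cd4-expressing clusters 75 were lower in the CD25+ comparison, and 434 were higher and 577 lower between the WT gates.

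Single genes that turned direction did so in Cd4-expressing clusters or in the Treg-like class of 2 clusters with doublets kept, among the alternatives run. In Cd4-expressing CD25+ cells the log2 ratio was −0.20 for Ifitm3, 1.23 for Scn4b, 0.06 for Il2rb, 0.21 for Cish, 0.12 for Ikzf2, 0.0897 for Tnfrsf18, 0.18 for Tnfrsf4, 0.41 for Nr4a1, 0.50 for Bcl2l11 and 0.31 for Cd24a. Between the WT gates it was 1.20 for Nr4a1, 0.47 for Cd69, 0.10 for Cd5 and 1.06 for Bcl2l11. In the other CD25+ cells it was −0.72 for Ifitm3, 0.94 for Emid1, 0.11 for Il2ra, 0.17 for Il2rb, 0.0320 for Cish, 0.0194 for Bcl2, 0.33 for Ikzf2, 0.0830 for Tnfrsf18, 0.17 for Tnfrsf4, 0.37 for Nr4a1, 0.43 for Bcl2l11 and 0.20 for Cd24a. In that class it was −0.00711 for Il2rb, −0.00407 for Tnfrsf18 and −0.00406 for Tnfrsf4. Of the single-gene ratios, 165 stayed within their counting interval and 10 moved with the reduced total, 116 and 59 with cells weighted equally, and 149 and 26 under the stricter cell filter. In Cd4-expressing clusters 38 stayed, 70 moved and 26 turned direction. Depth limits Il2, at 7 UMIs or fewer in each library.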

Other observations

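The tests of the heat shock pattern were chosen only after the result had been seen, and those of the genes apart in every class were written before it.

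In Cd4-low CD25+ cells, not compared by themselves so far, 11 of 12 interferon response genes were higher in the knockout-labelled library (median log2 ratio 1.43, 100th percentile), with Ifit1 4.22-fold, Usp18 3.97-fold, Ifit3 3.40-fold and Irf7 2.59-fold higher. H2-Q6 was 11.3-fold, H2-Q7 6.22-fold and Sorl1 5.75-fold higher, while Hspa8 was 5.39-fold, Scin 3.95-fold, Kremen1 3.64-fold and the chemokine receptor Ccr9 2.53-fold lower. Double-negative markers were lower in 14 of 18 (−0.22), αβ T cell markers higher in 10 of 10 (0.59) and proliferation genes higher in 18 of 18 (0.40). Cd4 itself was at only 2.26 CPM in the Cd4-low cells of both libraries together. The makeup of these cells differed too. A proliferating-like cluster held 8.66% of knockout-labelled and 4.55% of WT CD25+ cells, and a cluster led by Cpa3 and Lyl1 held 12.4% and 6.32%. Markers of myeloid and dendritic cells were lower in 9 of 10 (−0.62), with Cd74, the MHC class II invariant chain, at −2.42.

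Several further genes were chosen after their values had been seen. Zbtb16, the transcription factor PLZF of innate-like T cells, had 292 UMIs in the knockout-labelled and 10 in the WT CD25+ library (22.9-fold), nearly all in Cd4-low cells. Ccl5, a chemokine, was lower in the knockout-labelled library in the CD25− gate (3.46-fold), in the CD25+ gate (5.22-fold) and in Treg-like cells, with 1 UMI against 61 (log2 ratio −4.99, −10.3 to −2.45). Xcl1 was higher in knockout-labelled CD25− cells (55 against 5 UMIs, 13.4-fold) and in Cd4-expressing CD25+ cells (2.19-fold). In T cell receptor-signalled-like CD25+ cells, Gsta4 was 3.21-fold, Mid1 2.94-fold and Nr4a2 2.22-fold higher, and Nefh 6.24-fold, the kinase Pim1 2.56-fold and Tnfsf8 2.63-fold lower. Across genes, which are not independent replicates, the log2 ratios of the CD25− and CD25+ comparisons correlated at 0.61 over 6272 genes, with 37 genes at least 1.5-fold higher and 20 lower in both against 0.837 and 1.34 for independent lists.

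Heat shock genes were lower and the cold-inducible genes Rbm3 and Cirbp higher in the knockout-labelled libraries of both gates. A difference in cell makeup as the whole cause is argued against, since both directions held in 5 of 5 cell classes, with Rbm3 between 1.04 and 1.27 on the log2 scale. A difference in temperature or handling time between the preparations may also give this pattern: without Hspa8 and Hsph1 the heat shock factor targets still had medians of −0.30 and −0.43 in the CD25− and CD25+ gates. Genotype and preparation cannot be told apart here, because the labels give no preparation that held both, and a biological effect of the genotype stays open and untested.

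The 5 classes were mature and immature CD4 single-positive-like CD25− cells, and Treg-like, T cell receptor-signalled-like and Cd4-low CD25+ cells. Of 8480 genes tested in all 5 classes, 8 lay at least 2-fold apart in the same direction in each: Spaca1, Zfp951, Iigp1, Rbm3 and Mid1 were higher and Hspa8, Thy1 and Nefh lower in the knockout-labelled libraries. A passenger segment around Pdcd1 is argued against as their cause, as 0 of the 8 lie within 20 Mb of it, where 90 tested genes do. Segments that differ between the animals' strains may contribute elsewhere: none of the 8 has another within 2 Mb, at the 45.5th percentile of random sets. That met the bound written beforehand against this explanation, but the bound was wrong, since random sets of 8 also have a median share of 0 and no smaller share can occur. Hspa8 and Thy1, both on chromosome 9, lie 3.24 Mb apart, and whether the genes differ through strain, preparation or genotype cannot be told apart. Other combinations of class and gate were left out of the 5. Among them, Thy1 was not lower in T cell receptor-signalled-like CD25− cells (56.3 against 48.95 CPM, 26 and 19 UMIs), but was in mature CD4 single-positive-like CD25+ cells (101.3 against 394.5 CPM).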
